A study of Mus musculus with 32 samples.

How the data were processed

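RNA sequencing was measured in 32 libraries from cultures of mouse oligodendrocyte progenitor cells (OPCs), the dividing glial cells that give rise to myelinating oligodendrocytes. Per the labels, the cells were selected from cortex with an antibody against the O4 surface antigen, which OPCs and later oligodendrocyte stages carry and astrocytes do not, and were grown with the mitogens PDGF-AA and bFGF. Neonatal cells (nOPC) came from mice at postnatal day 5 and adult cells (aOPC) from mice at day 60. At each age there were untreated cultures, cultures given the vehicle dimethyl sulfoxide (DMSO, 0.02%) for 48 h, cultures given a pair of lysine acetyltransferase inhibitors (KATi, 5 µM garcinol with 0.2 µM NU-9056) for 48 h, and cultures given the H4K20 methyltransferase inhibitor A-196 at 5 µM for 48 h (SUV420i). No culture time is given for the untreated cells in the labels used here.

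The deposited table holds whole-number read counts per gene for 56980 Ensembl identifiers, with no normalization. The submitters' processing notes name CASAVA 1.8.2, Subread, featureCounts, DESeq2 and the mm10 build, without saying what each did. The annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads from a gene and from an overlapping or antisense gene cannot be told apart, and genes with close copies or pseudogenes may share reads. Gene symbols and coordinates came from a GENCODE annotation of GRCm38, the assembly that mm10 also denotes. It gave a symbol for 52073 identifiers and none for 4907, which took 2.37% of the counts. A single identifier without a symbol held 2.03% of all counts and between 0.3% and 3.92% of the counts of a library. It was kept in the tests and is not named.

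Library totals ran from 23.5 to 38.3 M counts, so at the shallowest library a gene at 1 CPM, or count per M counts of its library, rests on more than 20 reads. Counting error is small beside the spread between cultures at this depth, except for genes near 0.1 CPM. Mitochondrial transcripts took 1.69% to 4.5% of counts. No pair of libraries within a group held values within sampling noise of each other, the smallest chi-square per degree of freedom being 11.87, so each library counted once. The labels do not say whether replicates of a group came from separate animals, so p-values measure the spread between these cultures.

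Genes with enough counts for their group sizes were kept with filterByExpr (minimum count 10), leaving 20259 genes and 99.95% of the counts. Libraries were scaled with trimmed mean of M-values factors (0.951 to 1.03). All 32 libraries entered one edgeR quasi-likelihood fit with 8 groups and no block, in edgeR 4.0.16 and R 4.3.3, and each of the 12 planned comparisons was a contrast of that fit. Adjusted p-values are Benjamini-Hochberg values over the 20259 genes from edgeR's quasi-likelihood F test, and a gene was called below 0.05. Levels are mean CPM ± SD over libraries, and log2 fold changes carry their standard error (SE). The median log2 fold change over all genes was at most 0.039 in any comparison.

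There were 31 gene lists of 784 symbols, 699 of them measured, covering oligodendrocyte stages, cell cycle, chromatin enzymes, lipid synthesis, immune and stress programmes and markers of other cell types of the brain. They were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. Every list past camera with the preset correlation in the 12 planned comparisons lost that call with the estimated correlation. Lists, groups, tests, alternatives and the naming rule were fixed before the data were examined. The glycolysis list counts Aldoa under 2 identifiers.

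The naming rule took, for the age difference in DMSO and each inhibitor comparison, the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 2 and no overlap between the libraries of both groups, leaving out predicted, mitochondrial and ribosomal genes. It added up to 3 called members of each list past camera and 1 of any other, and 3 genes per direction for the interactions and the vehicle comparisons. In the blocked fit of KATi against SUV420i, the same direction in every letter took the place of no overlap for the largest rises and falls. Always named were Pdgfra, Cspg4, Gpr17, Mbp, Mki67, Hes5, Kat5, Ep300, Kmt5b and Kmt5c. A few genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

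The labels give each library a letter that recurs across treatments of an age. Letters were taken to pair libraries where every pair of same-letter libraries deviated together from its group means with a correlation over 0.1. This held for SUV420i and DMSO in adult cells (0.41 to 0.66 over 4 letters) and for KATi and SUV420i in adult cells (0.18 to 0.62), and in no other comparison. For these, a fit with the letter as a block is given beside the result. Contrasts of the age difference between cultures and of each inhibitor averaged over ages were added after the data were seen.

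Alternatives were DESeq2 size factors in edgeR, a DESeq2 1.42.0 Wald test, no filter on low counts, counts thinned to the smallest library, only the groups compared, the replicate block, a 2-fold minimum, and leaving out each library in turn. Added after the data were seen were the block fitted over all 32 libraries and a fit without the libraries of letters A and B, since the untreated groups hold neither letter. On simulated counts with 200 changed genes among 20259, the test of the age difference in DMSO recovered 36% of 1.5-fold, 72% of 2-fold and 96.5% of 4-fold changes. The corresponding shares were 24%, 75.5% and 96.5% for KATi in adult cells, 41.5%, 77.5% and 98.5% for KATi in neonatal cells and 6%, 55.5% and 93% for DMSO against untreated adult cells. With the block, KATi against SUV420i in adult cells recovered 71.5%, 95.5% and 100%. In each of 4 simulated comparisons camera called a planted list of 30 genes raised by 0.3 on the log2 scale and 0 of 30 unchanged lists. The simulated genes varied independently of each other, so this cannot show how often camera calls an unchanged list whose genes move together.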

Results

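Transcript counts were obtained from 32 cultures of O4-selected mouse OPCs in 8 groups. Adult cells comprised 2 untreated, 4 DMSO, 4 KATi and 4 SUV420i libraries, and neonatal cells 3 untreated, 5 DMSO, 5 KATi and 5 SUV420i libraries. Totals per library ranged from 24 to 25.5 M counts in untreated adult cells, 23.6 to 33.2 M in adult DMSO, 26.9 to 37.8 M in adult KATi and 31.8 to 35.6 M in adult SUV420i. The neonatal ranges were 24.7 to 29.6 M untreated, 26.2 to 38 M with DMSO, 23.5 to 32.9 M with KATi and 25.6 to 38.3 M with SUV420i. The targets of the inhibitors were expressed at both ages. Kat5, the acetyltransferase inhibited by NU-9056, stood at 45.4 ± 5.97 CPM (SD, n = 4) in adult and 52.7 ± 4.46 CPM (n = 5) in neonatal DMSO libraries. Ep300, an acetyltransferase inhibited by garcinol, stood at 173 ± 20.4 and 178 ± 17.6 CPM. Kmt5b and Kmt5c, which encode the H4K20 methyltransferases inhibited by A-196, stood at 95.5 ± 13.8 and 37.3 ± 5.17 CPM in adult and 91.2 ± 6.34 and 43 ± 2.88 CPM in neonatal cells. None of these 4 genes passed the test of the age difference in DMSO (adjusted p between 0.197 and 0.875).

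The first comparison asked how adult and neonatal OPCs differ in matched vehicle cultures. Gfap, the intermediate filament gene of astrocytes (chromosome 11, 102887336 to 102900912, GRCm38), was at 41.4 ± 35.2 CPM in adult (SD, n = 4) and 2.55 ± 1.64 CPM in neonatal cells (n = 5), a log2 fold change of 4 ± 0.82 (SE, adjusted p = 0.00274). Gfap split the adult libraries by letter: over all adult groups letters A and B lay between 6.74 and 17.3 CPM and letters C and D between 39.2 and 211 CPM. The complement gene C4b rose by 3.46 ± 0.61, the transcription factor gene Sp9 by 3.12 ± 0.44, Cp, which encodes the copper carrier ceruloplasmin, by 2.83 ± 0.49, and the angiotensinogen gene Agt by 2.7 ± 0.38. Cspg4, which encodes the NG2 proteoglycan of OPCs, was lower in adult cells at 337 ± 162 against 704 ± 93.1 CPM (log2 fold change -1.06 ± 0.28, adjusted p = 0.0136). It was not called without adult DMSO replicate 4 (-0.85, adjusted p = 0.074).

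Among the genes lower in adult cells, the G protein subunit gene Gng2 stood at 6.88 ± 4.04 against 56.2 ± 17.3 CPM (log2 fold change -3.02 ± 0.43) and Tgfb1i1, which encodes a focal adhesion protein, at 1.02 ± 0.914 against 7.98 ± 1 CPM (-3 ± 0.44). Jph4, a junctophilin gene, and AW551984 changed by -1.87 ± 0.22 and -1.88 ± 0.4. The homeobox gene Six3 (-2.15 ± 0.38) and Six3os1 (-3.26 ± 0.65) overlap on opposite strands of chromosome 17 (85613608 to 85629302 and 85600651 to 85618398), so their reads cannot be separated without strand. The non-coding Sox1ot, which overlaps Sox1, rose by 2.55 ± 0.38 with the same uncertainty. In all, 2584 of 20259 genes were called, 1324 higher and 1260 lower in adult cells.

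Of 26 cholesterol synthesis genes 22 fell, and 25 fell when adjusted over the list alone (camera adjusted p = 7e-29; adjusted p = 0.052 with an estimated correlation). They included Acat2, a thiolase gene, at 87.6 ± 18.9 against 191 ± 25.2 CPM (log2 fold change -1.12 ± 0.18). Fdps changed by -1.33 ± 0.16, but it has pseudogenes that may share its reads. Of 54 genes of G2 and M phase 22 fell and of 43 S phase genes 10 fell, or 29 and 20 when adjusted over the list alone, with 0 rising (camera adjusted p = 1.8e-14 and 1.8e-10; adjusted p = 0.35 and 0.4 with an estimated correlation). Ube2c, a mitotic ubiquitin-conjugating enzyme gene, changed by -0.84 ± 0.19 and Mcm2, a subunit of the replicative helicase, by -0.75 ± 0.21. Mki67, a marker of dividing cells, was at 748 ± 363 against 1090 ± 436 CPM and did not pass (adjusted p = 0.403).

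Of 20 astrocyte genes 13 rose and 0 fell, or 15 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.7e-10; adjusted p = 0.052 with an estimated correlation). Of 29 interferon response genes 13 rose, or 17 when adjusted over the list alone (camera adjusted p = 3.3e-10; adjusted p = 0.052 with an estimated correlation). Several of the interferon genes lay below 1 CPM, such as Trim30a at 0.622 ± 0.288 against 0.0974 ± 0.137 CPM. B2m, which encodes the light chain of class I antigen-presenting molecules, rose from 44.3 ± 6.36 to 67.9 ± 13.1 CPM and the glutathione transferase gene Gstm1 from 85.6 ± 24.8 to 270 ± 61.9 CPM. Among the acetyltransferase genes Kat2a (-0.5 ± 0.12) and Kat7 (-0.38 ± 0.07) were lower and Kat2b (0.44 ± 0.11) higher in adult cells, and the maintenance DNA methyltransferase gene Dnmt1 changed by -0.72 ± 0.21. Kat2a, Kat2b and Dnmt1 were not called without adult DMSO replicate 3 or 4. With the replicate block in the DMSO groups Kat2a, Kat2b and Kat7 were not called.

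Mbp, which encodes myelin basic protein (chromosome 18, 82475146 to 82585637), was called at 142 ± 164 against 10.3 ± 6.15 CPM (log2 fold change 3.78 ± 1.09, adjusted p = 0.022). The adult libraries were split by letter: letters C and D lay between 163 and 365 CPM and letters A and B between 6.31 and 13 CPM over all adult groups, the latter within the neonatal range, which reached 30.8 CPM. Pdgfra (adjusted p = 0.18), Gpr17 (0.522) and Hes5 (0.79) did not pass. Without letters A and B, Pdgfra (log2 fold change -1.01, adjusted p = 0.000118) and Gpr17 (-1.54, adjusted p = 0.0404) were called. The count of called genes was 4094 without adult DMSO replicate 1, 975 without replicate 3, 1047 without replicate 4 and 1720 without neonatal DMSO replicate 1. It was 4592 without letters A and B and 1323 when only the DMSO libraries were fitted. Mbp was not called without adult DMSO replicate 3 or 4 (adjusted p = 0.0664 and 0.117). Nor was it called without neonatal DMSO replicate 1 or 2 (adjusted p = 0.0558 and 0.052) or with the replicate block in the DMSO groups (adjusted p = 0.0693).

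**Figure D1:**
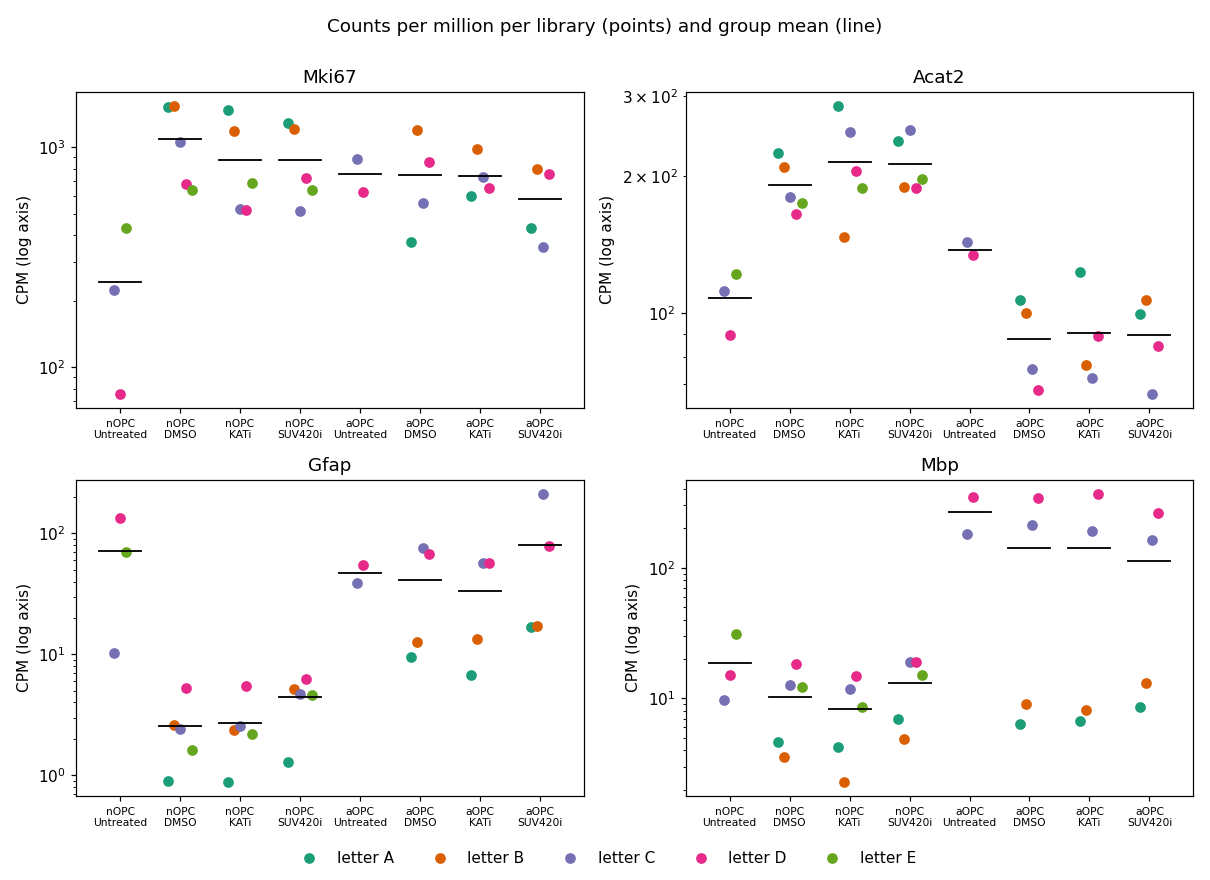
CPM (log axis) of Mki67, Acat2, Gfap and Mbp in each of the 32 libraries of the 8 groups, coloured by library letter, with a line at each group mean. Acat2 means were 138 CPM in untreated and 87.6 CPM in DMSO adult cells, and 108 and 191 CPM in neonatal cells, while Gfap and Mbp split the adult libraries by letter.

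The same age comparison in untreated cultures gave a different picture. Itga8, an integrin gene, was at 186 ± 23 CPM in adult (n = 2) and 20.6 ± 15.8 CPM in neonatal cells (n = 3). Its log2 fold change was 3.17 ± 0.75. The matrix genes Hmcn1 (3.11 ± 0.83) and Mmp2 (3.08 ± 0.82) were also called. S1pr3, a sphingosine 1-phosphate receptor gene, was lower in adult cells at 2.53 ± 0.185 against 29.4 ± 19.2 CPM (-3.54 ± 0.57), as were Tgfb1i1 (-2.94 ± 0.63) and the smooth muscle actin gene Acta2 (-2.89 ± 0.76). Several of these calls needed all of the untreated libraries: Hmcn1, Mmp2 and Acta2 were not called when any 1 of the 5 was left out. Their log2 fold changes then still ranged from 2.64 to 3.44, 2.46 to 3.48 and -3.79 to -2.36. Itga8 kept its call only without neonatal replicate 3 and Tgfb1i1 only without neonatal replicate 1 or 3, and S1pr3 lost it without adult replicate 2. Without adult replicate 2 the adjusted p was 0.356 for Hmcn1, 0.376 for Mmp2, 0.396 for Acta2, 0.245 for Itga8, 0.293 for Tgfb1i1 and 0.162 for S1pr3. In all, 312 genes were higher and 212 lower in adult cells. Of the always named genes, Gpr17, Hes5, Cspg4, Mbp and Kat5 were not called in this fit. They were called when only the untreated libraries were fitted (log2 fold changes -3.82, -2.13, -1.22, 3.81 and -0.35).

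Cell cycle and cholesterol genes leaned toward adult cells here. Of 43 S phase genes 2 rose and 38 rose when adjusted over the list alone (camera adjusted p = 1.5e-20; adjusted p = 0.41 with an estimated correlation). Of 26 cholesterol genes 3 rose and 16 rose when adjusted over the list alone (camera adjusted p = 1.8e-10; adjusted p = 0.41 with an estimated correlation). All 54 G2 and M phase genes had positive fold changes with 0 called by edgeR, also 0 when adjusted over the list alone (camera adjusted p = 2.4e-12; adjusted p = 0.54 with an estimated correlation). Mki67 was at 754 ± 183 against 244 ± 177 CPM without passing (adjusted p = 0.0922). Astrocyte genes leaned the other way, with a median of -0.59 and 0 of 20 called (camera adjusted p = 0.0015; adjusted p = 0.52 with an estimated correlation). The total of 524 fell to 43 and 4 without untreated adult replicates 1 and 2, and to 164 and 22 without untreated neonatal replicates 1 and 2. It was 3006 without letters A and B, 2952 when only the untreated libraries were fitted, and 1351 with DESeq2.

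Vehicle and untreated cultures were then compared within each age. In neonatal cells Mki67 rose in DMSO from 244 ± 177 to 1090 ± 436 CPM (log2 fold change 2.16 ± 0.49, adjusted p = 0.00567). Mki67 was not called without untreated neonatal replicate 2 (log2 fold change 1.72, adjusted p = 0.075). The immediate-early genes Egr1 and Arc were called at 2.51 ± 0.66 and 2.94 ± 0.9 on the log2 scale, but both had a single high library, neonatal DMSO replicate 2, at 369 and 29.1 CPM. Without it neither was called (Egr1 1.34, adjusted p = 0.0766; Arc 1.78, adjusted p = 0.154). Gfap was lower at 2.55 ± 1.64 against 71.6 ± 61.7 CPM (-4.79 ± 0.87), S1pr3 changed by -3.94 ± 0.4 and C4b by -3.66 ± 0.63. Of 43 S phase genes 36 rose, of 54 G2 and M phase genes 43 and of 26 cholesterol genes 23, or 42, 51 and 24 when adjusted over the list alone (camera adjusted p = 1.7e-21, 9.2e-25 and 6.6e-17; adjusted p = 0.22, 0.17 and 0.1 with an estimated correlation). Of 20 astrocyte genes 11 fell, or 15 when adjusted over the list alone (camera adjusted p = 1.9e-10; adjusted p = 0.1 with an estimated correlation). In all, 1288 genes rose and 1291 fell. The total of 2579 was 364 without untreated neonatal replicate 2, 1606 without DMSO replicate 1 and 1624 without DMSO replicate 2.

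Adult cells differed from their untreated cultures in fewer called genes, 9 higher and 53 lower in DMSO. Gdpd2, a phosphodiesterase family gene, rose from 6.03 ± 1.51 (n = 2) to 25.8 ± 12.3 CPM (n = 4), and Sez6l and Sned1 rose by 1.8 ± 0.37 and 1.74 ± 0.36. Liph, a phospholipase gene, was lower at 4.01 ± 0.349 against 17.3 ± 2.41 CPM (log2 fold change -2.1 ± 0.31), Bc1 changed by -1.96 ± 0.33 and Rasl11a by -1.71 ± 0.39. Cholesterol genes leaned lower in DMSO, with 3 of 26 called and 23 when adjusted over the list alone (camera adjusted p = 3e-26; adjusted p = 0.11 with an estimated correlation). S phase genes had a median of -0.53 with 0 of 43 positive, and G2 and M phase genes a median of -0.3 with 6 of 54 positive, with 0 called in either list by edgeR, also when adjusted over the list alone (camera adjusted p = 3.5e-13 and 1.7e-06; adjusted p = 0.41 and 0.57 with an estimated correlation). Mki67 was at 748 ± 363 and 754 ± 183 CPM, with an SE of 0.53 on the log2 scale. Astrocyte genes had a median of 0.55 with 0 of 20 called, and 3 rose when adjusted over the list alone (camera adjusted p = 0.00022; adjusted p = 0.25 with an estimated correlation). These were Agt (1.86 ± 0.52), Atp1b2 (0.87 ± 0.28) and Slc1a2 (0.95 ± 0.33), chosen after their values were seen. The total of 62 was 3 to 12 without untreated adult replicate 1 or 2 or DMSO replicate 3, and 211 without DMSO replicate 2. It was 1613 without letters A and B, 285 with DESeq2 and 0 with edgeR fitted on these groups only. The self-test of the full fit recovered 6% of 1.5-fold changes here.

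The age difference thus differed between the libraries labelled DMSO and untreated, and this was tested as an interaction added after the data were seen. It called 2204 genes, 1013 with a more positive and 1191 with a more negative age difference in DMSO. Adult levels of Acat2 were 138 ± 6.35 CPM untreated and 87.6 ± 18.9 CPM in DMSO, and neonatal levels 108 ± 16.6 and 191 ± 25.2 CPM. The difference of the age differences was -1.48 ± 0.3 (adjusted p = 0.00462). When adjusted over the list alone, 25 of 26 cholesterol, 43 of 43 S phase and 51 of 54 G2 and M phase genes were more negative (camera adjusted p = 1.3e-32, 3.9e-28 and 1.9e-24; adjusted p = 0.051, 0.19 and 0.19 with an estimated correlation). Of 20 astrocyte genes 15 were more positive (camera adjusted p = 1.6e-10; adjusted p = 0.073 with an estimated correlation). Across genes, which are not independent replicates, the 2 age differences correlated with r = 0.06 and rho = -0.02. The interaction count was 542 and 195 without untreated adult replicates 1 and 2, 650 without untreated neonatal replicate 2 and 1128 without adult DMSO replicate 3, and it was 3848 without letters A and B.

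A smaller set of genes separated the ages in both kinds of culture. Called in both were 101 genes, 36 higher and 19 lower in adult cells in both, and 46 in opposite directions. Independent lists would share 20.4 and 13.2 genes in the 2 shared directions and 13.9 and 19.4 in the opposite ones, where 23 and 23 were found. The following were chosen after their values were seen. Zdbf2 and Ndn, both imprinted genes, were lower in all 14 adult than in all 18 neonatal libraries, Ndn at 33.9 ± 4.66 against 90.4 ± 22.7 CPM in DMSO (log2 fold change -1.41 ± 0.23) and -1.12 ± 0.31 untreated. Tfap2a, Pax9 and Isl2, genes of developmental transcription factors, were higher in all 14 adult than in all 18 neonatal libraries, though below 10 CPM on average, with DMSO fold changes of 5.37 ± 0.72, 3.78 ± 0.55 and 3.42 ± 0.59 on the log2 scale. Gpd1, which encodes glycerol-3-phosphate dehydrogenase, was likewise higher at 136 ± 46.8 against 34.5 ± 10.2 CPM in DMSO and at 1.99 ± 0.42 on the log2 scale untreated. Nkx2-2, a transcription factor gene of the oligodendrocyte lineage, changed by -0.91 ± 0.21 and -1.17 ± 0.29.

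**Figure D2:**
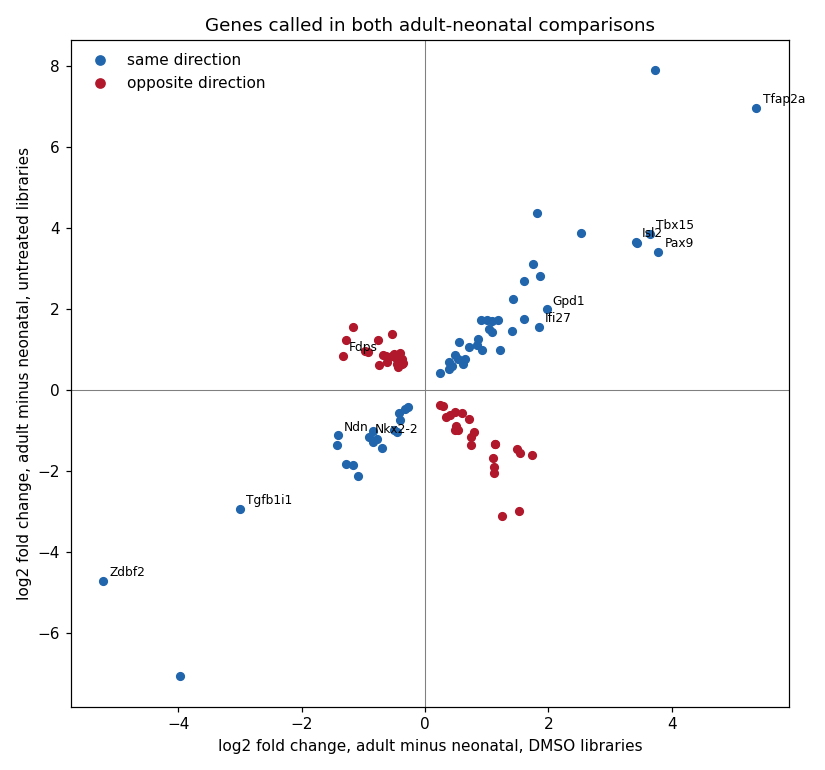
Log2 fold change of adult over neonatal cells in DMSO (horizontal) and untreated (vertical) cultures for the 101 genes called in both. Of these, 55 lie in the quadrants of equal sign, among them Tfap2a, Pax9, Zdbf2 and Ndn, and 46 in the other quadrants.

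KATi treatment for 48 h was compared with DMSO to ask what acetyltransferase inhibition changes at each age. Without a block no gene was called in adult cells by edgeR (0 called, 224 at an unadjusted p under 0.05) or by DESeq2 (0), and none in neonatal cells by edgeR (0 called, 2593 at an unadjusted p under 0.05) against 5 by DESeq2 (Crip2, Mgmt, Dcxr, Fbxw9 and 5830487J09Rik, chosen after their values were seen). Genes of the OPC stage leaned lower and S phase genes leaned higher at both ages, while Mki67 was at 743 ± 169 with KATi against 748 ± 363 CPM with DMSO in adult and at 878 ± 431 against 1090 ± 436 CPM in neonatal cells. In neonatal cells 4 of 20 OPC markers fell when adjusted over the list alone, with 0 called over all genes (camera adjusted p = 0.0057; adjusted p = 0.49 with an estimated correlation). They were Tnr, which encodes tenascin-R, at 214 ± 44.7 against 418 ± 142 CPM (n = 5 each, log2 fold change -0.96 ± 0.29), Lhfpl3 (-0.5 ± 0.17), Sox5 (-0.47 ± 0.15) and Sox6 (-0.44 ± 0.14), all chosen after their values were seen.

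Of 27 p53 target and cell cycle arrest genes 8 rose in neonatal KATi cultures when adjusted over the list alone, with 0 called over all genes (camera adjusted p = 0.00036; adjusted p = 0.49 with an estimated correlation). Chosen after their values were seen, Cdkn1a, the gene of the cell cycle inhibitor p21, was at 393 ± 55 against 242 ± 72 CPM, Gdf15 at 4.42 ± 1.71 against 1.94 ± 0.61 CPM and Bax, a pro-apoptotic gene, at 143 ± 11.9 against 111 ± 15.4 CPM. S phase genes had medians of 0.26 in neonatal and 0.23 in adult cells, with 37 and 42 of 43 positive and 0 called at either age, also when adjusted over the list alone (camera adjusted p = 0.00011 and 1.5e-11; adjusted p = 0.66 and 0.47 with an estimated correlation). In adult cells OPC markers had a median of -0.21 with 0 of 20 called (camera adjusted p = 0.0017; adjusted p = 0.47 with an estimated correlation). Gpr17, a receptor gene of committed OPCs, was at 237 ± 176 with KATi and 459 ± 309 CPM with DMSO in adult cells.

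SUV420i treatment was compared with DMSO in the same way. Again edgeR called 0 genes in adult cells (376 at an unadjusted p under 0.05; DESeq2 0) and 0 in neonatal cells (1577 at an unadjusted p under 0.05; DESeq2 1, the phosphofructokinase gene Pfkl, chosen after its value was seen). In adult cells fatty acid synthesis genes leaned higher: 2 of 17 rose when adjusted over the list alone, Fasn, the fatty acid synthase gene, at 1190 ± 54.1 against 914 ± 71.9 CPM (n = 4 each, log2 fold change 0.38 ± 0.12) and the desaturase gene Scd2 at 5660 ± 661 against 4420 ± 512 CPM, both chosen after their values were seen (camera adjusted p = 4.8e-06; adjusted p = 0.11 with an estimated correlation). Antigen presentation genes had medians of 0.19 in adult and 0.23 in neonatal cells, with all 18 members positive in neonatal cells (camera adjusted p = 0.0027 and 0.0026; adjusted p = 0.66 and 0.43 with an estimated correlation). Tap2 alone passed when adjusted over the list alone, in neonatal cells, at 5.19 ± 0.541 against 3.58 ± 0.58 CPM. G2 and M phase and S phase genes leaned lower in adult cells, with medians of -0.15 and -0.09 and 0 called by edgeR, also when adjusted over the list alone (camera adjusted p = 4.8e-06 and 0.035; adjusted p = 0.94 and 0.94 with an estimated correlation). With the letter as a block, adult SUV420i against DMSO still had 0 genes called by edgeR (1597 at an unadjusted p under 0.05), and 143 without letter A. In that fit 7 of 17 fatty acid genes rose when adjusted over the list alone, and astrocyte and Schwann cell and ependymal genes, with medians of 0.09 and 0.19, also passed camera with 0 called over all genes (camera adjusted p = 0.0026 and 0.031; adjusted p = 0.68 and 0.49 with an estimated correlation).

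Neither inhibitor's effect was shown to differ between ages: edgeR called 0 genes for the KATi interaction (251 at an unadjusted p under 0.05; DESeq2 0) and 0 for the SUV420i interaction (486; DESeq2 0). Of the lists, heat shock and unfolded protein response genes passed camera for the SUV420i interaction, with a median of -0.18 and 0 of 24 called (camera adjusted p = 0.011; adjusted p = 0.94 with an estimated correlation). For Kat5 the KATi interaction was -0.2 ± 0.16 and for Ep300 the SUV420i interaction was 0.38 ± 0.19 on the log2 scale, neither called. Averaged over ages, a contrast added after the data were seen, KATi had 0 genes called by edgeR (2094 at an unadjusted p under 0.05; DESeq2 1, Cgref1, chosen after its value was seen) and SUV420i had 1 gene called (1137 at an unadjusted p under 0.05; DESeq2 10). It was Atp2b3, a plasma membrane calcium pump gene, chosen after its values were seen, with a log2 fold change of 1.35 ± 0.35 in adult and 1.76 ± 0.33 in neonatal cells at a level near the floor. It was no longer called with thinned counts, with no filter on low counts, with only these groups or without letters A and B. The effects of KATi in the 2 ages, which share no library, correlated across genes with r = 0.26 and rho = 0.34 (permutation p = 0.063 for r and 0.04 for rho over 252 labellings, unadjusted). Those of SUV420i correlated with r = 0.12 and rho = 0.15 (permutation p = 0.1 and 0.071).

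KATi and SUV420i cultures were also compared directly, since they hold inhibitors of different chromatin enzymes at the same time point. Without a block edgeR called 0 genes in adult cells (871 at an unadjusted p under 0.05; DESeq2 3, Ehd2, Msn and Adarb1, chosen after their values were seen) and 0 in neonatal cells (1149; DESeq2 9). With the letter as a block, adult cells had 347 genes called, 101 higher and 246 lower with KATi (3238 at an unadjusted p under 0.05). Angpt2, which encodes the vascular ligand angiopoietin 2, was at 5.85 ± 2.57 with KATi and 2.35 ± 1.1 CPM with SUV420i (n = 4 each, log2 fold change 1.32 ± 0.16, higher in 4 of 4 letters). The extracellular matrix gene Tnc (1.12 ± 0.13), Anxa3 (1.14 ± 0.12) and Col18a1 (1.05 ± 0.15) were also higher in 4 of 4 letters. Lower with KATi in all 4 letters were Gpr17 at 237 ± 176 against 610 ± 558 CPM (-1.11 ± 0.17, adjusted p = 0.0115), Gsg1l (-1.63 ± 0.18), Cyp4f15 (-1.02 ± 0.11), Gjd2 (-1.05 ± 0.16), Mc5r (-1.04 ± 0.15) and C4b (-1.02 ± 0.2). All of these were picked from called genes that moved the same way in all 4 letters. Their agreement over letters was thus set by the choice and adds no support.

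By list in the blocked fit, OPC markers fell in 2 of 20 members, or 9 when adjusted over the list alone (camera adjusted p = 7.6e-06; adjusted p = 0.25 with an estimated correlation), namely Neu4, a sialidase gene, (-1.83 ± 0.22) and Tnr (-0.73 ± 0.11). Inhibitors of oligodendrocyte differentiation fell in 3 of 19, or 11 when adjusted over the list alone with 1 rising (camera adjusted p = 4.5e-07; adjusted p = 0.25 with an estimated correlation): the Notch target Hes5 (-0.97 ± 0.11), Id4 (-0.62 ± 0.11) and Sox4 (-0.36 ± 0.07). Fatty acid synthesis genes fell in 4 of 17, or 8 when adjusted over the list alone with 1 rising, including Fasn (-0.46 ± 0.07) and Scd1 (-0.4 ± 0.08) (camera adjusted p = 1.6e-05; adjusted p = 0.28 with an estimated correlation). Astrocyte genes fell in 4 of 20, or 8 when adjusted over the list alone, including Gfap (-1.01 ± 0.21) and the water channel gene Aqp4 (-0.92 ± 0.14) (camera adjusted p = 1.8e-09; adjusted p = 0.3 with an estimated correlation). Neuron and neuroblast genes fell in 1 of 22, or 7 when adjusted over the list alone (camera adjusted p = 0.00013; adjusted p = 0.25 with an estimated correlation), namely Rbfox3, which encodes the neuronal nuclear antigen NeuN (-0.8 ± 0.15). Wnt and Tgfb pathway targets fell in 2 of 16, namely Sfrp1 (-0.69 ± 0.09) and Apcdd1 (-0.74 ± 0.16), or 5 when adjusted over the list alone, with Nkd1, Dkk3 and Skil, chosen after their values were seen. The list's camera adjusted p was 5.6e-05 (adjusted p = 0.25 with an estimated correlation). Committed and premyelinating genes fell in 2 of 19, Gpr17 and Lims2 (-0.81 ± 0.14), or 7 when adjusted over the list alone (camera adjusted p = 4.1e-05; adjusted p = 0.29 with an estimated correlation). Cell cycle genes leaned higher, with 25 of 43 S phase genes rising when adjusted over the list alone and 0 called over all genes (camera adjusted p = 2.9e-21; adjusted p = 0.38 with an estimated correlation). The blocked fit has 3 residual degrees of freedom per comparison of 4 pairs. Leaving out letter A, B, C or D gave 68, 471, 37 and 107 called genes.

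**Figure D3:**
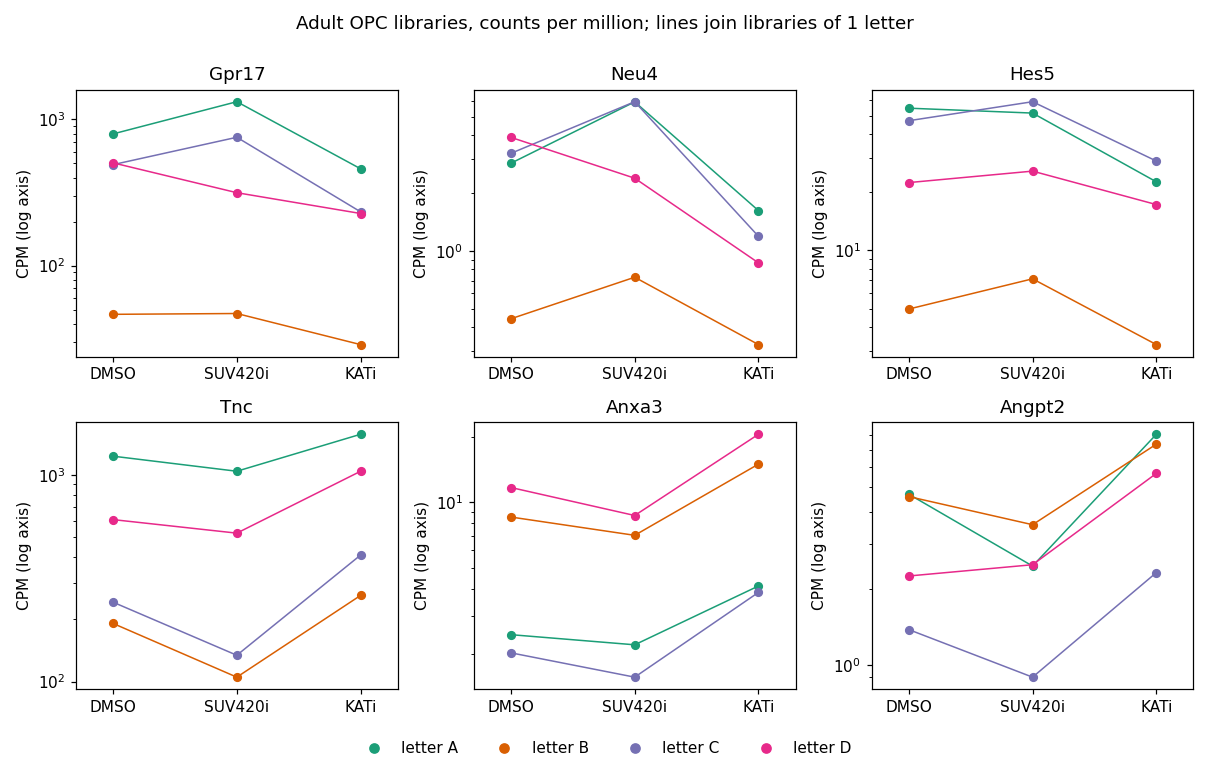
CPM of Gpr17, Neu4, Hes5, Tnc, Anxa3 and Angpt2 in adult DMSO, SUV420i and KATi cultures, each line joining the libraries of a letter. In all 4 letters Gpr17, Neu4 and Hes5 were lower and Tnc, Anxa3 and Angpt2 higher with KATi than with SUV420i. Gpr17, Tnc, Anxa3 and Angpt2 were picked for the same direction in all 4 letters.

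To ask whether inhibitor effects run along or against the age difference, log2 fold changes were correlated across the 20259 genes, with the age difference from untreated libraries so that no library was shared. For KATi r was 0.27 in adult (exact permutation p = 0.2, 70 labellings) and 0.08 in neonatal cells (permutation p = 0.77, 252 labellings), and for SUV420i -0.08 (p = 0.8 by exact permutation) and -0.14 (permutation p = 0.67). The values of rho were 0.28, 0.06, -0.1 and -0.16. Over these 4 relations each adjusted permutation p was 0.8. Over only the 524 genes called in the untreated age difference, r was 0.64 for KATi in adult (exact permutation p = 0.11) and 0.54 in neonatal cells (permutation p = 0.33). For SUV420i it was -0.28 (exact permutation p = 0.6) and -0.09 (permutation p = 0.9). KATi and SUV420i share their DMSO libraries, and their effects correlated with r = 0.37 in adult and 0.57 in neonatal cells, where simulated unchanged groups gave 0.5 and 0.5. The covariance was 0.0252 against a simulated 0.0598 in adult and 0.0558 against 0.0439 in neonatal cells, and with the DMSO libraries split between the inhibitors the mean r was -0.31 and 0.14.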

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

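The tests of exchanged age labels, of missing letters, of astrocyte genes, of myelin genes between letters and of the axis between DMSO and untreated cultures were chosen after the values were seen, as was the age by culture contrast. The first form of the test of exchanged labels came out in favour of an exchange, and its second form and bounds were set after the first result and both percentages were seen. The last form and its bounds were set before its own values were seen but after those 2 results. It met its bound against an exchange, but that bound was wrong for this design, as was noticed after the value was seen. The tests with a cell cycle covariate and over other splits of the libraries were set before their results were seen.

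The age difference turned between DMSO and untreated cultures, with 2204 genes called by the test of the difference of differences. On the log2 scale, DMSO minus untreated, the difference of the age differences was -2.16 for Fdps, -1.48 for Acat2, -1.72 for Hk2, -1.47 for Stc2, -1.07 for Asns and -0.94 for Shmt2. It was -2.17 for Mki67, -1.82 for Uhrf1, -1.68 for Mcm5, -1.52 for Mcm2, -1.44 for Hmgb2, -1.21 for Ube2c, -1.23 for Pimreg, -1.37 for Dnmt1, -2 for Mycn, -0.73 for Kat2a and -0.47 for Kat7. Negative values were also found for Six3 (-1.84), Jph4 (-1.53), Ier2 (-1.64) and Itga8 (-2.86). The astrocyte list members Gfap (4.6), Agt (3.76) and Gjb6 (3.76) were positive. So were C4b (5.02), Col4a5 (1.96), Foxj1 (1.46), Sox1ot (2.9), Bmpr1b (1.86), Thrsp (1.94), Nlrc5 (2.25), H2-T23 (1.9), Gstm1 (2.45), Gsta4 (2.12), Gabrb1 (2.88), S1pr3 (4.35) and Ifit3b (5.29), the last from levels below 1 CPM.

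Letters A and B, missing from the untreated groups, are argued against as the cause, since the median of the S phase genes was -1.51 with all libraries and -1.42 (SD 0.38) without these letters. An exchange of age labels between the untreated adult and neonatal cultures cannot be told apart from a true turn, since of 357 genes that parted all 12 treated adult from all 15 treated neonatal libraries 33 (9.24%) placed all 5 untreated libraries on the side of their label, within the first bound for an exchange (under 10%), and 67 (18.8%) on the other side, short of the second (over 50%). In the last form the difference between letters D and C correlated across genes with treated libraries of the same age label by 0.3 more than with the other age in untreated adult and by 0.45 more in untreated neonatal cells, but this needs letters to mean the same within an age, the treatments overlapped in neonatal cells (-0.18 to 0.39 against -0.37 to 0.17), and with 1 library per letter the 4 possible orders of the letters are too few to exclude chance. Of single genes, chosen after their values were seen, Zdbf2, Ndn and Tgfb1i1 were lower and Tfap2a and Pax9 higher in all 14 adult than in all 18 neonatal libraries, Mbp was at 181 and 348 CPM in untreated adult and at most 30.8 CPM in any neonatal library, and Xist went with the label in letter D (492 and 32.8 CPM in adult and neonatal) but in untreated adult letter C, at 412 CPM, lay in the range of treated neonatal letter C (228 to 862 CPM) and below treated adult letter C (847 to 1120 CPM). Fewer cycling cells in the untreated neonatal cultures could account for part of the pattern: with a cell cycle covariate the median of the cholesterol genes went from -1.41 (SD 0.46) to -0.81 (SD 0.44) and the calls from 2204 to 3, but the covariate is nearly confounded with the groups, so this cannot be told apart, and astrocytes in those cultures could account for 18 of 20 astrocyte genes lying at least 0.3 lower in DMSO, although OPCs express several of these, such as Slc1a3 at 997 CPM in DMSO, while an effect of culture that depends on age, the unstated culture time of the untreated cells and an exchange of single libraries stay open and untested.

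Mbp parted the adult libraries by letter rather than by treatment, with letters A and B at 6.31 to 13 CPM and letters C and D at 163 to 365 CPM. Mature oligodendrocytes or their RNA in the letter C and D cultures are argued against as the whole cause only by single genes at low levels. Mobp and Mog, abundant in myelin, rose from 0.903 and 0.381 CPM to only 1.89 and 1.01 CPM. The difference was 4.86 on the log2 scale for Mbp and a median of 0.73 (SD 1.21) over 14 other myelin genes. That median cannot decide, since some of the 14 were already high in letters A and B and added RNA would move them little. Among these were Gsn, at 111 CPM in letters A and B and 127 CPM in C and D, and Cnp, at 254 and 426 CPM. Of the 14, 4 rose by over 1 on the log2 scale, among them Gjc3 (4.33), Fa2h (2.18) and Cldn11 (1.17). Letters are not described in the labels beyond their name, and no biological explanation was tested.

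A relation of the adult difference between KATi and SUV420i with that between DMSO and untreated adult cultures was not shown. Across genes KATi minus SUV420i correlated with DMSO minus untreated with r = -0.31 and rho = -0.34 (exact permutation p = 0.14, 70 labellings). Without adult KATi replicate 4 r was -0.2, and without replicates 1, 2 and 3 it was -0.27, -0.28 and -0.37. A shared axis of culture state and the pull of that single library may both contribute, and these values cannot be told apart with 4 libraries a group.

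Single libraries stood apart from the rest of their group for 25 of 289 values tested in the groups, for the genes reported here. The bounds used give about 1 in 20 by chance for independent, normally distributed values. CPM need not be normally distributed and many of the values share a library, so the chance rate here is not known. Neonatal DMSO replicate 2 was highest for Arc (29.1 CPM), Egr1 (369 CPM), Cp (30.5 CPM), Fas (10.9 CPM), Trim30a (0.332 CPM), Asns (120 CPM), Ier2 (34.8 CPM), Gabrb1 (10.7 CPM) and Slco1a4 (0.905 CPM). Other neonatal DMSO libraries stood apart for Klk6 (0.0517 CPM, replicate 4), Ifit3b (0.124 CPM, replicate 5) and Kat2a (93.5 CPM, replicate 1, lowest). In neonatal SUV420i cultures, Hes5 was lowest in replicate 2 (3.45 CPM) and Kat5 highest in replicate 3 (72.5 CPM). In adult DMSO cultures replicate 2 was highest for Uhrf1 (169 CPM) and lowest for Sparc (433 CPM), and replicate 1 lowest for Kat2b (26.4 CPM). In adult KATi cultures replicate 2 was highest for Col18a1 (22.7 CPM), replicate 3 highest for Mc5r (4.75 CPM) and replicate 1 lowest for H2-K1 (16 CPM). In adult SUV420i cultures replicate 2 was highest for Col18a1 (8.22 CPM) and Slc3a2 (210 CPM), replicate 1 for Tnr (784 CPM) and Scn3a (35.9 CPM) and replicate 3 for Scd2 (6650 CPM).

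Other splits of the same libraries were counted for each comparison of groups of 3 or more. For the age difference in DMSO, 1 of 100 splits, the real one, gave as many called genes (2584, highest other 1057). For DMSO against untreated in neonatal cells it was 1 of 56 (2579, highest other 70). Both shares are under 0.05, but they are not adjusted over the comparisons, and the splits take libraries as exchangeable across letters. Chance could not be excluded for the others, compared by genes at an unadjusted p under 0.05. Their splits mix letters, so they can miss a change that is shared within letters. Swaps within letters were not run for KATi against DMSO. The shares were 29 of 35 splits for KATi in adult cells (224, highest other 5154) and 10 of 100 in neonatal cells (2593, highest other 4955). For SUV420i they were 25 of 35 in adult (376, highest other 4759) and 14 of 100 in neonatal cells (1577, highest other 4380). The same held for KATi against SUV420i, with 18 of 35 in adult (871; 3124) and 33 of 100 in neonatal cells (1149; 5850), for the interactions, with 96 of 100 for KATi (251; 5971) and 70 of 100 for SUV420i (486; 3818), and for KATi averaged over ages, with 14 of 100 (2094; 6273). For SUV420i averaged over ages 5 of 100 splits called as many genes as the real one (1; highest other 912). The split with 912 called put letters A and C against B and D in adult cells. For KATi against SUV420i in neonatal cells the split with 5850 genes at an unadjusted p under 0.05 put letters A and B together. Both point to a structure of the samples by letter. The most genes called in any other split of that neonatal comparison was 1666, not necessarily in the same split. For the blocked adult comparisons the 8 possible splits are too few for a share under 0.05. For KATi against SUV420i the real split called 347 genes, 1 of 8, and the highest other 0, and for SUV420i against DMSO the real split had 1597 genes at an unadjusted p under 0.05, 3 of 8, and the highest other 2289.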

How the results depend on the processing

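The replicate block over all 32 libraries and the fit without letters A and B were chosen after the values were seen, as were the age by culture contrast and the means over ages. For the changes below the cause was not tested unless stated.

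With DESeq2 size factors, thinned counts or no filter, the counts of called genes stayed within 1.5 times, except SUV420i averaged over ages (1 gene, then 0 when thinned and 0 with no filter) and the age difference in untreated cultures (524, then 334 with no filter). A 2-fold minimum, which removes smaller changes, left 796 genes for age in DMSO, 287 for age untreated, 35 and 849 for DMSO against untreated in adult and neonatal cells and 1254 for the age by culture contrast. Fitting only the groups compared gave 1323 for age in DMSO, 2952 for age untreated, 0 for DMSO against untreated in adult cells and 0 for SUV420i over ages. Without letters A and B these were 4592, 3006, 1613 and 0, and 3848 for age by culture. DESeq2 called 1351 for age untreated, 285 for DMSO against untreated in adult cells, 5 for KATi and 1 for SUV420i in neonatal cells, 3 and 9 for KATi against SUV420i in adult and neonatal cells, and 1 and 10 for KATi and SUV420i over ages.

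With the replicate block in the groups compared, age in DMSO had 552 genes, age untreated 3934, DMSO against untreated in adult cells 5815 and age by culture 5092. KATi had 1 (Gpr17, named by the rule) in adult and 355 in neonatal cells, with Pdgfra, Gpr17 and Hes5 among them, KATi against SUV420i 347 and 243, and KATi and SUV420i over ages 719 and 218. The replicate block over all 32 libraries gave 4168, 2914, 3927 and 6224 for the first 4 and 4867 for DMSO against untreated in neonatal cells. KATi had 1 (Stx11) in adult and 983 in neonatal cells, SUV420i 3 (Stc2, Tmem158 and Fam69c) and 99, KATi against SUV420i 322 and 545, and the means over ages 1167 and 311; these 4 genes were chosen after their values were seen. The block changed no other count by over 1.5 times. As a hint from the data, not the design, libraries correlated best with their own letter in 3 of 4 for KATi in adult cells, 3 of 5 for KATi, 2 of 5 for SUV420i and 3 of 5 for KATi against SUV420i in neonatal cells, 1 of 4 for age in DMSO and 1 of 3 for DMSO against untreated neonatal cells.

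Leaving out 1 library at a time gave 975 to 4094 genes for age in DMSO, 4 to 758 for age untreated, 3 to 211 and 364 to 2877 for DMSO against untreated in adult and neonatal cells and 195 to 2920 for age by culture. KATi over ages, KATi against SUV420i in neonatal cells and SUV420i in neonatal cells had 0 to 1, SUV420i over ages 1 to 2 and the other inhibitor contrasts 0 to 0. The fewest were Foxd2, Foxd2os, Cdon and Tfap2a for age untreated and Col5a1, Uaca and AC113540.1 for DMSO against untreated adult cells. The inhibitor calls were Cgref1 or Lmna for KATi over ages, Gramd1b for KATi against SUV420i, Atp2b3 for SUV420i and also Pfkl for SUV420i over ages, all chosen after their values were seen. A lone untreated adult library was assumed to vary like the other groups.

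Of gene lists, 107 passed camera over the 12 comparisons, 0 with the estimated correlation, 39 with fry and 158 with the replicate block. With fry, 0 of 31 lists passed for KATi or SUV420i against DMSO at either age, and 0 for the inhibitor by age interactions. For KATi against SUV420i fry passed 1 list in adult and 0 in neonatal cells. With DMSO libraries for the age difference, which shares them, r became -0.27 for KATi in adult, -0.01 for KATi in neonatal and 0.09 for SUV420i in neonatal cells. With split controls the inhibitors correlated at -0.31 in adult and 0.14 in neonatal cells, values that are pushed down where letters pair libraries. Of 3056 alternatives for 177 values of the named genes reported here, 2806 kept direction and call, 205 lost the call, 45 gained it and 0 turned, and 30 of 80 called genes kept their call in every alternative set before the data were seen. Depth limits genes near the floor, such as Klk6, Xaf1, Ifit3b and Atp2b3.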

Other observations

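The observations on sex-linked transcripts were chosen after the values were seen, and no explanation was tested for them.

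Gene groups not described above also differed between DMSO and untreated neonatal cultures. Of 34 matrix and collagen genes 9 fell and 1 rose in DMSO, or 9 and 2 when adjusted over the list alone (camera adjusted p = 9.4e-06; adjusted p = 0.1 with an estimated correlation), and of 29 interferon response genes 9 fell, or 10 when adjusted over the list alone (camera adjusted p = 3.7e-06; adjusted p = 0.1 with an estimated correlation). Of 23 genes of repressive histone methyltransferases 10 rose, or 11 when adjusted over the list alone (camera adjusted p = 9.4e-06; adjusted p = 0.1 with an estimated correlation). In adult cells 24 genes of heat shock and the unfolded protein response were lower in DMSO by a median of -0.3 with 0 called, or 3 when adjusted over the list alone (camera adjusted p = 1.7e-06; adjusted p = 0.11 with an estimated correlation).

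Most letters held their own levels of sex-linked transcripts across treatments. Xist, the transcript that silences an X chromosome in female cells, lay at 43.5, 51.7 and 64.4 CPM in the adult DMSO, KATi and SUV420i cultures of letter A and at 1070, 1370 and 1180 CPM in those of letter B, where the Y-linked Eif2s3y was at 6.52, 6.89 and 5.11 CPM against 67.2, 63.4 and 69.4 CPM in letter A. In neonatal cells letter D had 32.8 CPM of Xist untreated, 47.8 with DMSO, 22.2 with KATi and 51 with SUV420i, and letter E 548, 630, 560 and 399 CPM. Letter C was less even in neonatal cells, with 862 CPM in DMSO and 228 and 238 CPM with KATi and SUV420i. Letter D was uneven in adult cells, with Xist at 983 CPM in DMSO, 469 with KATi and 829 with SUV420i and the Y-linked Ddx3y at 32.6, 13.7 and 21.2 CPM. The KATi library of that letter lay nearer to its untreated library (492 and 14.3 CPM), and it forms 1 of the 4 pairs of the blocked KATi and SUV420i fit. Elsewhere these levels are a hint from the data, not the design, that libraries of a letter and age share a mix of animals. Both sexes contributed to most cultures, and the adult untreated libraries, of letters C and D, stood at 412 and 492 CPM.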
